A study of Homo sapiens with 5 samples.

How the data were processed

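The libraries were made by poly(A) site sequencing, in which reads begin at the junction between an mRNA's 3′ end and its poly(A) tail. Per the labels' protocols, 10 µg of total RNA was fragmented for 10 min, reverse transcribed from an oligo(dT) primer, and cDNA of 120 to 200 nt was circularised, reopened with a restriction enzyme and amplified to a product of about 200 bp. Reads were single-end; the labels give their length as 150 nt in one place and 100 nt in another. The cells were HEK293T, a human embryonic kidney line grown in 5% serum, and knockouts were made with CRISPR/Cas9, per the labels. The 5 libraries were 1 control, 2 CFIm59 (gene CPSF7) knockout cell lines and 2 CFIm68 (gene CPSF6) knockout cell lines, and the labels call each pair separate cell lines. The spread behind the edgeR, DESeq2, camera and fry p-values below is therefore the spread between cell lines of 1 genotype. Fisher's exact and permutation tests compare genes, bootstrap intervals resample genes, and none of them use that spread.

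The deposited values were raw read counts per poly(A) site and library, with 1 column per library and no column of other samples (0 columns without a sample). The authors named hg19, TopHat2 2.1.0 and deepTools 2.4, per the submitters' processing notes, with no role for each. How sites were called, how internal priming at genomic A stretches was handled, and which annotation release named the genes are not given in the sources used here. The authors classed each site as last exon, intron or upstream exon, per the file headers. Coordinates are the hg19 positions as deposited; whether they count from 0 or 1 is not stated. The table listed 290072 site entries for 31173 genes. These were 272248 distinct sites, of which 15981 were listed more than once under other genes or classes; the 17824 repeated listings always held 0 reads, so a site's reads stood under the first gene only. This placed reads of 7905 shared sites under 1 gene each, and 2883 genes had a listed site whose reads stood under another gene. Of the distinct sites, 67011 had no read and 44020 had 10 or more reads over the 5 libraries. For 44 symbols, reads lay at more than 1 locus, and each locus was kept apart. No molecular identifiers were used, so intervals and floors cover counting error only.

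For alternative polyadenylation, the pair of sites with most reads over the 5 libraries was taken for each gene, and the upstream site on the gene's strand was called proximal. Genes entered when both sites together averaged 20 or more reads per library and each site averaged 5 or more, which left 5869 genes. Proximal and distal counts were fitted with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with a term per library and a site-by-group term. A positive log2 value is a change of the proximal to distal ratio toward the proximal site. For expression, reads were summed per gene, filtered with filterByExpr to 14636 genes, scaled by TMM and fitted with the same test. Levels are given in CPM, the usual rescaling of read counts by library total, after TMM. All 5 libraries entered each fit and shared 1 spread per gene; the lone control was thereby assumed to vary like the knockout lines. All adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2-sided, with a threshold of 0.05. Values of the knockouts are means ± SD over 2 cell lines, and shares in the control carry a Wilson 95% interval. A share of 0 also carries its floor of 3 reads. A fold against a group whose libraries were all at 0 was computed against a floor of 3 reads in each library and is a lower bound; a fold against 1 to 3 reads carries its exact 95% counting interval. Common dispersions were 0.0173 for site pairs and 0.0218 for genes.

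Gene lists, main tests and the rule for naming genes were fixed before the data were examined. Named genes were, for site use against the control, the 12 to proximal and the 6 to distal with the largest change in percentage points, among genes that passed the test, with both lines on the same side and 50 or more reads per library on average, so single libraries can hold fewer. Between the knockouts they were 6 each way with no overlap of libraries. For expression they were the 8 higher and 8 lower with the largest log2 change and a mean count of 20 or more, or 6 each way between the knockouts. The genes CPSF6, CPSF7 and NUDT21, and up to 4 members of each list, were added; symbols starting LOC, LINC, MIR, SNOR, RNU or RNA, or holding -AS, were left out, and some genes the rule selects are not reported here. The 22 lists were CFIm subunits, other cleavage and polyadenylation factors, SR proteins, hnRNP proteins, earlier CFIm targets (from literature, not chosen on these samples), cytosolic ribosomal proteins, replication-dependent histones, p53 targets, the unfolded protein and integrated stress response, cholesterol synthesis, interferon-stimulated genes, cell cycle, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, heat shock, neuronal genes, fibroblast and mesenchymal genes, epithelial genes, blood cell genes and kidney progenitor genes. Lists were tested on expression with camera (limma 3.58.1) at its preset correlation, and again with an estimated correlation and with fry, whose directional test asks for change on balance 1 way and whose mixed test asks for change in either direction; the blood cell list, with 2 measured genes, was not tested. On site use, the share of members called to proximal was compared with the other tested genes by Fisher's exact test, 2-sided, with Benjamini-Hochberg adjustment over lists.

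The fits were tested on simulated counts drawn from the real means, with 100 genes changed at each of 2 sizes. For site use over 5869 genes, log2 changes of 1 and 2 were recovered in 2% and 31% of genes in the CFIm68 knockout against the control, and in 9% and 43% between the knockouts. For expression over 14636 genes the shares were 18% and 76%, and 40% and 80%. False calls were 1 and 5 for site use and 0 and 5 for expression, and the unchanged comparison gave 0. A gene with no call can therefore still hold a change of that size. The share recovered also depends on how many genes change, since the adjustment is stricter when few do. More genes passed in the data, so these shares are not the recovery there.

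Alternatives were DESeq2 1.42.0, RLE scaling, scaling by library size only, another setting of the edgeR fit, other read minimums, a minimum change, diffSpliceDGE over all sites, the most proximal with the most distal site, merging sites within 40 nt, last exon sites only, genes without shared sites, reads of shared sites under every gene, mitochondrial genes left out, a replicate block and leaving out each knockout library. The alternatives on site class, shared sites, library size and mitochondrial genes were added after the data were seen. Sequence around the sites was not analysed here. Summaries and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.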

Results

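Cleavage factor Im (CFIm) is a 3′ end processing factor built from CFIm25 (gene NUDT21), which binds UGUA in RNA, and either CFIm59 (CPSF7) or CFIm68 (CPSF6). CFIm59 and CFIm68 carry domains rich in arginine and serine, like those of SR splicing proteins. The series asked how these subunits act on poly(A) site choice, with HEK293T cells lacking CFIm59 or CFIm68. Reads at poly(A) sites were counted in 1 control library and 2 cell lines of each knockout. The control held 2924266 reads. The CFIm59 knockout lines held 1673687 and 2585923 reads, and the CFIm68 knockout lines 2727728 and 2078376. Mitochondrial sites took 9.05% of reads in the control, 9.79% and 10.8% in the CFIm59 knockout lines and 8.02% and 6.01% in the CFIm68 knockout lines. Of the nuclear reads, 89.5% lay at last exon sites in the control, 88.8% and 88.0% in the CFIm59 knockout lines, and 89.1% and 91.2% in the CFIm68 knockout lines. The labels call the lines of 1 genotype separate cell lines, and each was kept as a replicate. Across genes, which are not independent replicates, log expression correlated at 0.960 and 0.965 between lines of a genotype. The correlation was 0.891 between the control and the CFIm59 knockout and 0.943 between the control and the CFIm68 knockout.

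The targeted genes were read first, as a check of the labels. CPSF6 fell in the CFIm68 knockout, from 119 CPM in the control to 46.5 ± 1.57 CPM (SD, n = 2; log2 -1.35, SE 0.25, adjusted p = 0.000511). It stood at 141 ± 1.00 CPM in the CFIm59 knockout (adjusted p = 0.575). The remaining CPSF6 reads of the CFIm68 knockout lay mostly at the upstream sites of the gene on chromosome 12. The site at 69663450 held 57 reads in the control and 52 and 50 in these lines, whereas that at 69668134 held 86 in the control and 22 and 11. CPSF7 stood at 59.4 CPM in the control and 61.6 ± 9.08 CPM in the CFIm59 knockout (adjusted p = 0.947). It rose to 165 ± 53.8 CPM in the CFIm68 knockout (log2 1.47, SE 0.29, adjusted p = 0.000921). NUDT21 stood at 119 CPM in the control, 74.3 ± 9.63 CPM in the CFIm59 knockout (adjusted p = 0.0583) and 137 ± 4.14 CPM in the CFIm68 knockout (adjusted p = 0.76). Between the knockouts, CPSF7 was higher by log2 1.42 (adjusted p = 4.23e-06) and NUDT21 by log2 0.88 (adjusted p = 0.00161) in the CFIm68 knockout. These tests were edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Which part of each gene was edited is not given in the sources used here. The 3′ reads of CPSF7 therefore do not check the CFIm59 knockout label.

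**Figure D1:**
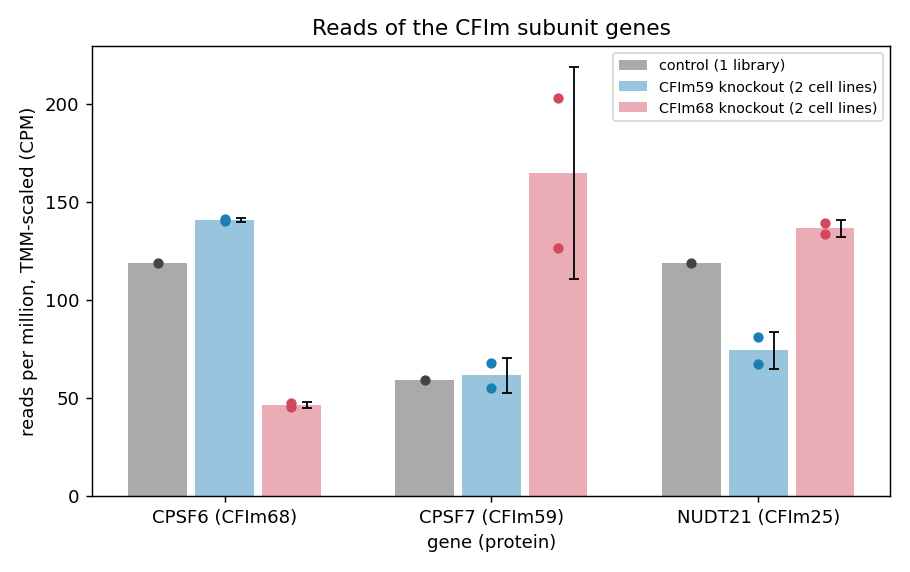
Expression of CPSF6, CPSF7 and NUDT21 in CPM (y axis) in the control (1 library), the CFIm59 knockout and the CFIm68 knockout (2 cell lines each). Bars are group means, points are libraries and error bars are SD over 2 lines, and CPSF6 stands at 46.5 CPM in the CFIm68 knockout against 119 CPM in the control.

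The CFIm68 knockout was compared with the control to see which genes change poly(A) site when CFIm68 is lost. Most changed genes moved to the proximal site. PUM2, a Pumilio repressor of mRNAs (chromosome 2, minus strand, last exon sites at 20451049 and 20448500), used its proximal site for 2.17% of reads in the control (95% interval 0.742 to 6.2) and 1.70 ± 1.04% in the CFIm59 knockout. It used it for 84.7 ± 1.13% in the CFIm68 knockout (SD, n = 2; log2 7.89, SE 0.62, adjusted p = 8.97e-16). UBQLN1, an adaptor that brings ubiquitinated proteins to the proteasome (chromosome 9, sites at 86276325 and 86274883), went from 11% (8.08 to 14.7) to 86.8 ± 0.225% (log2 5.72, SE 0.46, adjusted p = 1.49e-15). NADK2, the mitochondrial NAD kinase, rose from 18.2% to 96.0 ± 3.41% (adjusted p = 4.67e-11). The m6A reader YTHDF3 rose from 9.76% to 84.4 ± 2.51% (adjusted p = 2.7e-11), and IREB2, an iron regulatory protein, from 18.4% to 88.9 ± 1.71% (adjusted p = 2.47e-13). The other named genes were C21orf91, OSBPL8, IDS, ARFGEF2, ESYT2, CAMSAP2 and PRRC1, which reached from 75.5% in ARFGEF2 to 92.1% in C21orf91. In the other direction, MAF, a leucine zipper transcription factor (chromosome 16, minus strand, sites at 79630369 and 79628232), fell from 79.7% at an intron site (69.2 to 87.3) to 31.5 ± 0.532% (log2 -3.08, SE 0.55, adjusted p = 8.36e-06). AEBP2, EXOC8, CA8 and RIF1 were also named to distal, CA8 with 25 control reads and a move to distal in the CFIm59 knockout as well. NUDT21 itself moved from 38.9% (32.8 to 45.4) to 75.1 ± 1.63% (log2 2.23, SE 0.41, adjusted p = 1.19e-05). With last exon sites only, another pair of AEBP2 gave log2 3.31, and the most proximal and most distal sites gave 1.16 in EXOC8 and 0.92 in RIF1. With DESeq2 the calls of CA8 and RIF1 ended (adjusted p of 0.103 and 0.0683, in ranges over the alternatives of 0.00213 to 0.103 and 4.02e-08 to 0.376).

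Of 5869 tested genes, 1483 changed to the proximal site and 184 to the distal site. Of these, 1482 and 184 had both lines on 1 side of the control. Chance gives this for 66.7% of unselected genes. These genes had passed a test on the same libraries, which favours such agreement, so the counts add no support. The median change was 28.0 percentage points (quartiles 18.4 and 40.8) to proximal and -20.9 points (-32.3 and -12.8) to distal. Median proximal use over all tested genes was 34.3% in the control and 49.3% and 46.8% in the lines. Pairs with both sites in the last exon class changed to proximal in 29.0% of 4675 genes, and other pairs in 10.5% of 1194. The share that changed to proximal was 4.92% for sites under 250 nt apart, 27.8% at 250 to 1000 nt, 42.5% at 1000 to 4000 nt and 17.6% beyond. Across genes, the change correlated with log distance at a Spearman rho of 0.0765, or 0.25 in last exon pairs. DESeq2 called 752 to proximal and 38 to distal, and minimums of 100 reads for both sites and 20 for each left 518 and 85.

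Fixed lists were then read for the same comparison. SRSF7, an SR splicing protein (chromosome 2, sites at 38972035 and 38970746), rose from 81.1% (78.5 to 83.5) to 99.4 ± 0.178% proximal use (adjusted p = 7.77e-13). In all, 5 of 12 SR proteins changed to proximal and 0 to distal, SRSF6, TRA2B and SRSF2 included. The hnRNP proteins gave 8 of 17 to proximal, HNRNPA0 and HNRNPK included, and 1, HNRNPD, to distal. SYNCRIP went from 43.8% to 91.0 ± 2.44%. Among earlier CFIm targets, 5 of 10 changed to proximal, with LAMC1, SMOC1, TIMP2 and DICER1. In the same list VMA21, an assembly factor of the vacuolar ATPase, went from 25.2% to 82.1 ± 5.73% (adjusted p = 7.75e-12). Other cleavage and polyadenylation factors gave 4 of 12 to proximal, or 2 without CFIm68 knockout line 2, among them PCF11 from 28.3% to 66.7 ± 11.2%. Cholesterol synthesis gave 6 of 11, with HMGCS1 from 7.09% to 59.6 ± 2.17%, and cell cycle genes 6 of 18, with CCNA2 from 23.3% to 61.5 ± 2.18%. The unfolded protein and integrated stress response gave 3 of 8 (HSPA5, XBP1 and VEGFA), heat shock 3 of 9 (DNAJB1, HSPH1 and DNAJA1) and p53 targets 2 of 6 (MDM2 and TNFRSF10B). Immediate early genes gave 2 of 4 (FOS and JUN) and CFIm subunits 1 of 3 (NUDT21). Of 53 cytosolic ribosomal proteins, 2 changed to proximal, RPL37 among them, and 6 to distal, or 10 without CFIm68 knockout line 1. RPL23A fell from 83.8% to 65.5 ± 5.10%. The share of ribosomal proteins to proximal lay below that of the other genes by Fisher's exact test (adjusted p = 0.001). For every other list the adjusted p was 0.194 or more. The test took no account of site distance or of control use near 100%. RPL37A, for example, had sites 161 nt apart and 99.3% proximal use in the control, which leaves little room to rise. How many ribosomal pairs were of this kind was not examined, so the low share need not be a trait of these genes. Oxidative phosphorylation genes gave 2 to proximal and 4 to distal of 30, histones 0 and 1 of 4, glycolysis and hypoxia 0 and 1 of 8 (PDK1), and mitochondrially encoded genes 0 and 1 of 2. Neuronal genes gave 1 of 1 to proximal (NEFL), fibroblast genes 1 of 3 (COL5A1) and kidney progenitor genes 1 of 2 (SALL1). Epithelial genes gave 0 of 2 and interferon-stimulated genes 0 of 1, and no blood cell gene was tested. Adjusted over the list alone, the counts to proximal and distal were 6 and 0 for SR proteins, 9 and 1 for hnRNP proteins, 2 and 5 for ribosomal proteins, 4 and 0 for p53 targets, 7 and 0 for cell cycle genes, 2 and 3 for oxidative phosphorylation and 2 and 0 for kidney progenitor genes. The other lists kept their counts.

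The CFIm59 knockout was compared with the control for the same question about CFIm59. Here the changed genes moved mostly to the distal site. ZNF721, a zinc finger gene (chromosome 4, last exon sites at 438021 and 433780), fell from 56.8% proximal use in the control (45.9 to 67.0) to 6.51 ± 4.06% (SD, n = 2; log2 -4.36, SE 0.69, adjusted p = 1.53e-05). SLIT2, a ligand in axon guidance, fell from 48.4% (41.9 to 55.0) at an intron site to 4.61 ± 0.996% (adjusted p = 5.88e-09). In the other direction, SGSM3 (chromosome 22, sites at 40806107 and 40806288) rose from 5% (1.38 to 16.5) to 83.2 ± 2.86% (log2 6.39, SE 0.82, adjusted p = 6.94e-08). It stood at 4.76 ± 6.73% in the CFIm68 knockout. An intron site rose in SAE1, a subunit of the SUMO-activating enzyme, from 1.26% (0.490 to 3.19) to 33.6 ± 1.27% (adjusted p = 2.71e-09). Another rose in FAM35A (chromosome 10, sites at 88878998 and 88951220), from 0 of 130 reads, which allows a share of up to 2.31% at a floor of 3 reads (Wilson 95% interval up to 2.87%), to 35.2 ± 3.06% (adjusted p = 7.32e-08). Its share was also 0 in both CFIm68 knockout lines, where the same floor allows up to 4.11% and 4.48%. The other named genes were CA8, PLAA, SGCB and ATF7IP to distal, CA8 and ATF7IP with 25 control reads each. To proximal they were MPP6, EFNA1, CSNK1E, HIBCH, FBXO9, ATP2C1, CTD-2006C1.2, RP4-665J23.1 and RP11-846F4.12. CA8, PLAA and CTD-2006C1.2 passed the same way in the CFIm68 knockout, at 40.9 ± 9.76, 40.1 ± 7.63 and 32.2 ± 17.9%. Between the knockouts they did not pass the test (adjusted p of 0.398, 0.0754 and 0.461). Their changes in both rest on the 1 control library. EFNA1 has a site also listed under another gene, so its change cannot be assigned to it with certainty. Without CFIm59 knockout line 1 the calls of ATF7IP, CA8, FBXO9, HIBCH, MPP6 and RP11-846F4.12 ended (adjusted p from 0.0526 to 0.32), and without line 2 those of ATP2C1, CTD-2006C1.2, FBXO9 and HIBCH (0.0695 to 0.114). With DESeq2 the calls of ATP2C1, CSNK1E, EFNA1, FBXO9, HIBCH, PLAA, RP11-846F4.12 and SGCB ended (0.0622 to 0.356). With diffSpliceDGE over all sites those of the same genes but EFNA1 ended, and those of ATF7IP, CA8, CTD-2006C1.2 and MPP6 (0.081 to 0.467). With no minimum beyond 1 read ATF7IP, ATP2C1, CA8, FBXO9, HIBCH, MPP6 and RP11-846F4.12 lost the call (0.0527 to 0.148), and with the most proximal and most distal site ATP2C1, CSNK1E, CTD-2006C1.2, FBXO9, HIBCH and SGCB (0.0813 to 0.625). With last exon sites only, which pairs other sites, log2 was 0.23 for SLIT2, 0.02 for SAE1, -2.45 for MPP6 and -2.15 for CTD-2006C1.2.

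Of the 5869 genes, 60 changed to proximal and 316 to distal in the CFIm59 knockout. All had both lines on 1 side of the control, against 66.7% by chance in unselected genes. Selection by the test on the same libraries favours this, so it adds no support. The median change to distal was -23.3 percentage points (quartiles -30.3 and -15.7) and that to proximal 24.8 points (11.4 and 33.3). Median proximal use was 28.6% and 28.9% in the lines against 34.3% in the control. Last exon pairs changed to distal in 5.80% of genes and other pairs in 3.77%. By distance the share to distal was 0.439% under 250 nt, 4.01% to 1000 nt, 8.89% to 4000 nt and 6.17% beyond. The change correlated with log distance at a Spearman rho of -0.0862 across genes, and -0.227 in last exon pairs. The counts were 36 and 162 without CFIm59 knockout line 1, 35 and 129 without line 2, 8 and 14 with DESeq2, and 18 and 51 with diffSpliceDGE over all sites. Minimums of 100 reads for both sites and 20 for each left 36 and 203.

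Other cleavage and polyadenylation factors gave 6 of 12 to distal in the CFIm59 knockout and 0 to proximal, but 1 to distal without line 1. WDR33, a subunit of the factor that binds the poly(A) signal (chromosome 2, sites at 128522048 and 128463503), fell from 35.6% (28.3 to 43.5) to 4.92 ± 1.17% proximal use (adjusted p = 1.97e-05). CSTF2, a cleavage stimulation factor subunit, fell from 85.2% to 57.4 ± 8.51% (adjusted p = 0.0078), and PAPOLA, a poly(A) polymerase, from 13.2% to 4.24 ± 2.08% (adjusted p = 0.0158). CPSF2, RBBP6 and FIP1L1 fell as well. SRSF7 fell from 81.1% to 59.2 ± 0.253% (log2 -1.56, adjusted p = 0.00377), as the 1 of 12 SR proteins that changed. Among 17 hnRNP proteins SYNCRIP and HNRNPH3 fell, and among 9 heat shock genes DNAJA1, from 68.1% to 35.1 ± 2.4% (adjusted p = 0.000241). Ribosomal proteins gave 4 of 53 to proximal, RPL28, RPL37A and RPL23A included, and 2 to distal, RPS23 included. The count to proximal was 2 without CFIm59 knockout line 1 and 10 without either CFIm68 knockout line. The share of ribosomal proteins to proximal passed Fisher's exact test against the other genes (adjusted p = 0.0418), and the other lists had 0.829 or more. That test does not address changes to distal, and it took no account of site distance or control use. Oxidative phosphorylation gave 1 to proximal and 2 to distal of 30, and cell cycle genes 1 (MCM7) and 1 (RRM2) of 18. Glycolysis gave 1 (GPI) and 0 of 8, neuronal genes 0 and 1 of 1 (NEFL, from 67.2% to 29.7 ± 2.04%), and mitochondrially encoded genes 0 and 1 of 2. The remaining tested lists, CFIm subunits and earlier CFIm targets included, gave 0 and 0 with edgeR. Adjusted over the list alone, the counts were 5 and 2 for ribosomal proteins, 0 and 1 for earlier CFIm targets, 1 and 3 for cell cycle genes, 0 and 2 for mitochondrially encoded genes and 1 and 1 for heat shock. The other lists kept their counts.

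**Figure D2:**
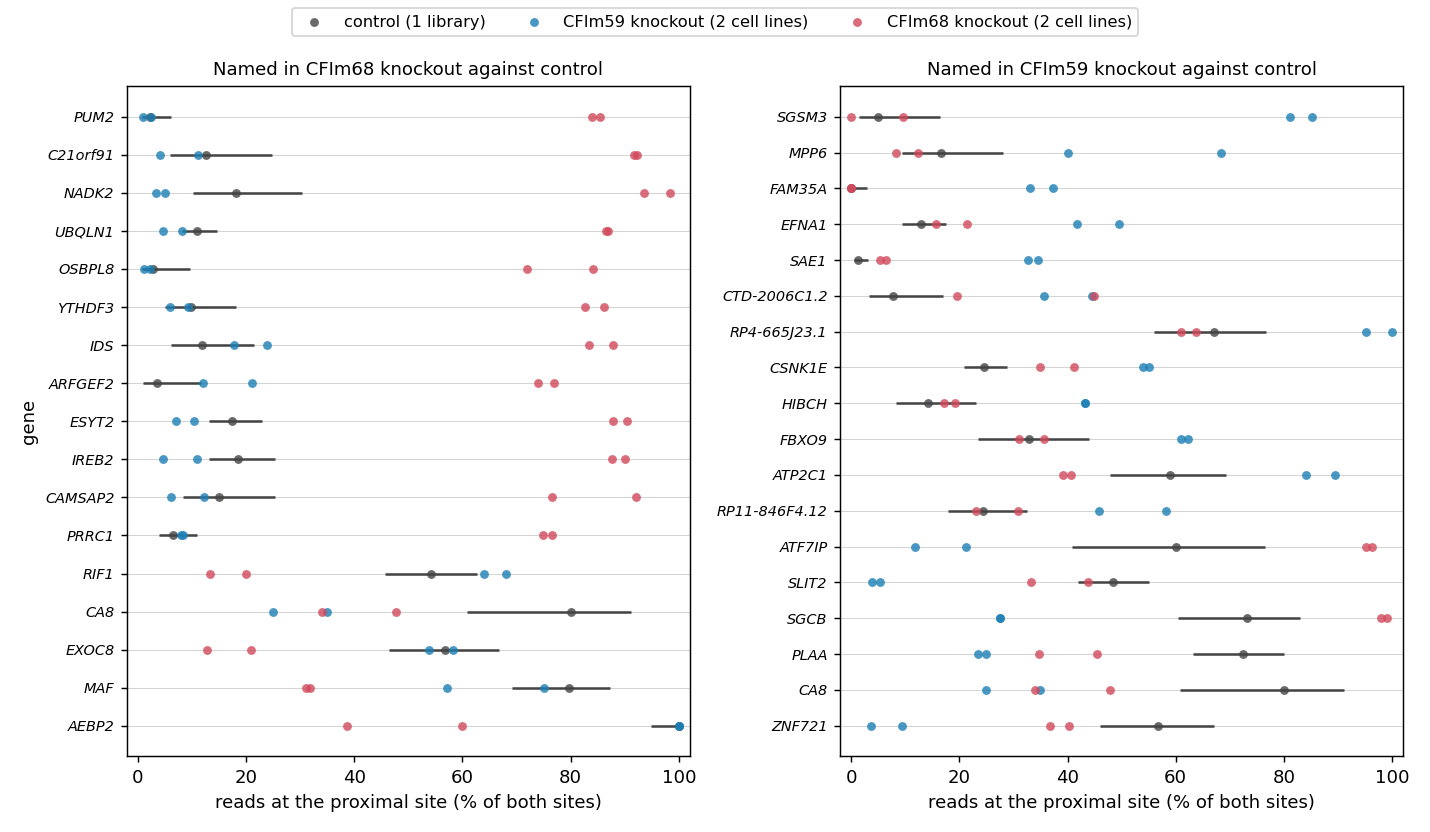
Share of reads at the proximal site (x axis, percent of the reads of both sites) of the genes named for the CFIm68 knockout (left) and the CFIm59 knockout (right), against the control; points are libraries and bars are the Wilson 95% interval of the control. PUM2 stands at 2.17% in the control and 84.7% in the CFIm68 knockout, and SGSM3 at 5% in the control and 83.2% in the CFIm59 knockout.

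The knockouts were compared with each other, which tests whether their effects on site use differ. NAB1, a repressor that binds EGR transcription factors (chromosome 2, sites at 191555423 and 191557491), used its proximal site for 23% of reads in the control (14.2 to 34.9). It used it for 2.12 ± 0.924% in the CFIm59 knockout and 88.0 ± 0.869% in the CFIm68 knockout (log2 8.37, SE 0.64, adjusted p = 5.06e-18). SSX2IP, a centrosome protein (chromosome 1, sites at 85113023 and 85110656), stood at 50% in the control, 11.6 ± 11% in the CFIm59 knockout and 95.7 ± 1.03% in the CFIm68 knockout (log2 7.27, adjusted p = 1.19e-14). PUM2 and NADK2 were higher in the CFIm68 knockout by log2 8.33 and 9.20 (adjusted p of 3.52e-22 and 1.96e-19), and EPHA7 and C21orf91 were named with them. SGSM3 was lower, by log2 -6.39 (adjusted p = 2.17e-13), named together with AEBP2, RIF1, GCFC2 and KIAA1524. With other pairs of sites these last genes turned or lost the call: AEBP2 gave log2 2.79 and KIAA1524 -0.19 (adjusted p = 0.847) with last exon sites only, and GCFC2 3.41, KIAA1524 2.78 and RIF1 0.73 with the most proximal and most distal sites. Of 5869 genes, 2390 stood further to proximal in the CFIm68 knockout and 364 further to distal. Of these, 2378 and 361 had no overlap of lines, which chance gives for 33.3% of unselected genes. Selection by the test on the same libraries favours this too, so it adds no support. The count to distal was 235 without CFIm59 knockout line 2 and 190 with DESeq2, and minimums of 100 reads for both sites and 20 for each left 752 and 148.

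Among the lists, other cleavage and polyadenylation factors stood further to proximal in the CFIm68 knockout than in the CFIm59 knockout in 8 of 12 genes, WDR33, CSTF2 and PCF11 included. Earlier CFIm targets did so in 8 of 10, or 5 without CFIm59 knockout line 2 and 5 without CFIm68 knockout line 1. SR proteins gave 8 of 12 with SRSF10 the other way, and hnRNP proteins 8 of 17 with HNRNPD the other way. None of these shares passed Fisher's exact test against the other genes (adjusted p of 0.339, 0.134, 0.339 and 1). Ribosomal proteins gave 7 to proximal and 18 to distal of 53 (adjusted p = 0.000346), with RPL23A at 94.5 ± 1.06% in the CFIm59 knockout and 65.5 ± 5.10% in the CFIm68 knockout. Oxidative phosphorylation gave 5 and 9 of 30 (adjusted p = 0.0843), with 4 to distal without CFIm59 knockout line 2. Cholesterol synthesis gave 6 and 0 of 11, cell cycle genes 7 and 3 of 18, and p53 targets 3 and 0 of 6. The unfolded protein and integrated stress response gave 5 and 0 of 8, but 3 and 1 to proximal without CFIm59 knockout lines 1 and 2, and 2 without CFIm68 knockout line 1. Heat shock gave 3 and 1 of 9, glycolysis 2 and 2 of 8, kidney progenitor genes 2 and 0 of 2, immediate early genes 2 and 0 of 4, and histones 0 and 1 of 4. CFIm subunits, mitochondrially encoded genes, neuronal genes and fibroblast genes gave 1 and 0 each, and epithelial and interferon-stimulated genes 0 and 0. For these lists Fisher's exact test gave an adjusted p of 0.497 or more. Adjusted over the list alone, earlier CFIm targets gave 9 and 0, ribosomal proteins 8 and 18, p53 targets 4 and 0, and the other lists the same counts.

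Both comparisons against the control share 1 library, so their changes would correlate with no effect at all. In 20 simulations of unchanged groups, all 5 libraries were drawn anew, the shared control included. There the changes correlated at 0.640 across genes, with a covariance of 0.277 (SD 0.0111). The deviation of the real control is not known from them. The observed correlation was -0.0471 (Spearman -0.0887) and the covariance -0.0860, below the simulated values. With minimums of 100 reads for both sites and 20 for each, the correlation was -0.340 (Spearman -0.349), and no simulation was run for them. Both lists held 152 genes to proximal in the CFIm68 knockout and to distal in the CFIm59 knockout, where independent lists would share 79.8. That number takes every tested gene as equally likely to be called. Calls to proximal in the CFIm68 knockout were 42.5% at 1000 to 4000 nt and 4.92% under 250 nt. Calls to distal in the CFIm59 knockout were 8.89% and 0.439%. Part of the excess over 79.8 may therefore come from pairs in which either call is more likely. To proximal in both went 9 genes (15.2 for independent lists), to distal in both 16 (9.91), and in the reverse combination 4 (1.88). With 1 control library the controls could not be split. A shared control moves both changes the same way, so part of the excess to distal in both may come from it. With minimums of 100 reads for both sites and 20 for each that excess was absent, with 7 genes against 11.5.

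**Figure D3:**
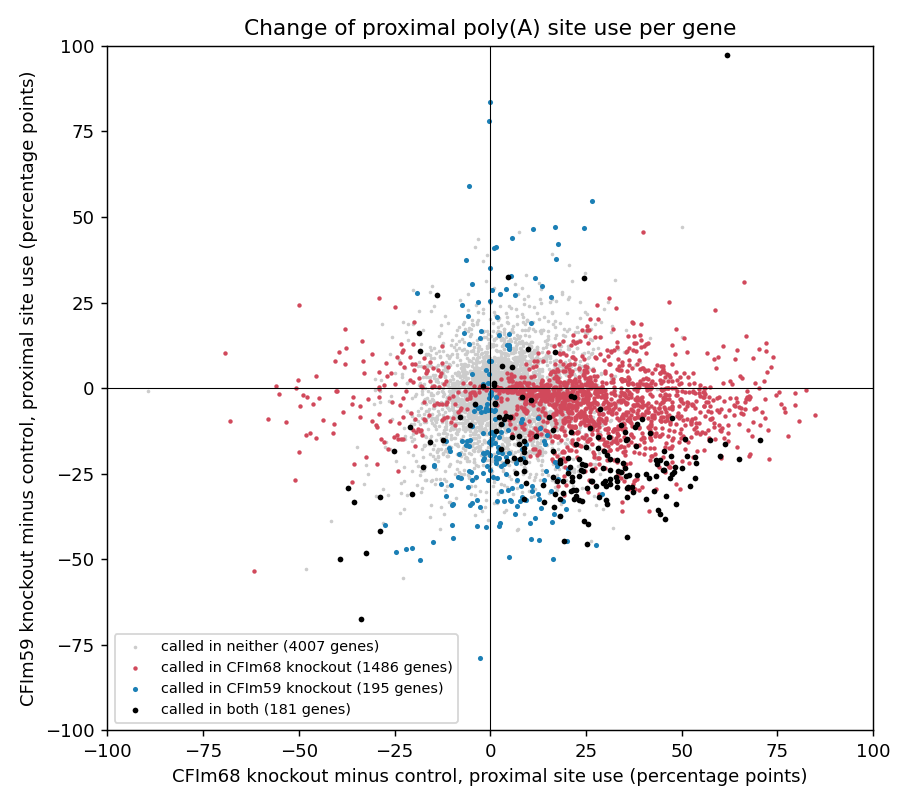
Change of proximal site use per gene, CFIm68 knockout minus control (x axis) against CFIm59 knockout minus control (y axis), both in percentage points; each of the 5869 points is a gene, coloured by the comparison in which it passed the test. In the lower right lie the 152 genes that passed to proximal in the CFIm68 knockout and to distal in the CFIm59 knockout.

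Gene expression was read from the same counts, summed per gene. In the CFIm68 knockout against the control, MID1, a microtubule-associated ubiquitin ligase, fell from 386 CPM to 40.6 ± 11.9 CPM (SD, n = 2; log2 -3.24, SE 0.25, adjusted p = 1.7e-13). DDR2, a collagen receptor kinase, fell from 37.7 to 1.18 ± 0.203 CPM (log2 -4.96, adjusted p = 4.34e-09). BEX1 went from 50 to 0.173 ± 0.244 CPM, 258-fold lower (counting interval 45.6 to 10284; adjusted p = 8.06e-12). MFAP2, a microfibril protein, went from 7.84 CPM to 0, at least 6.65-fold lower (adjusted p = 2.59e-05). LMCD1 rose from 2.24 to 26.0 ± 1.20 CPM (log2 3.51, SE 0.53, adjusted p = 1.9e-05). Genes without a control read that rose included CDO1, a cysteine dioxygenase, to 4.4 ± 0.611 CPM (at least 3.93-fold), and ENPP2, which encodes autotaxin, to 3.79 ± 0.990 CPM (at least 3.38-fold). LYPD1 reached 3.63 ± 1.72 CPM (at least 3.24-fold; adjusted p = 0.0186, and 0.0664 without CFIm68 knockout line 2, in a range of 0.00488 to 0.0664 over the alternatives). The other named genes were RP11-53O19.3, RP11-321N4.5 and GCSHP3 lower and AC012501.2, PRAC2, RAB38 and AF003625.3 higher. All reads of GCSHP3 and AF003625.3, and some of RP11-321N4.5 and AC012501.2, lay at sites shared with other genes, so the changes of the first 2 cannot be assigned to them. Against the same control library, CDO1, ENPP2, LYPD1, AC012501.2, PRAC2 and RAB38 rose in the CFIm59 knockout as well, to 27.3 ± 3.24, 26.9 ± 6.80, 27.3 ± 3.24, 38.4 ± 4.78, 32.7 ± 0.918 and 13.8 ± 1.52 CPM. Their rises in both knockouts rest on that 1 library. PRAC2 had an adjusted p of 0.00877, and 0.0552 without CFIm68 knockout line 1, in a range of 0.00242 to 0.0552. HSPA1A was lower, with 0 reads in both lines and 7 in the control (at least 2.22-fold, fitted log2 -5.67, adjusted p = 0.0107). Without line 1 or line 2 the fitted log2 was -5.59 and -5.69 and the call ended (adjusted p of 0.0812 and 0.0503, in a range of 0.00388 to 0.0812). Its near-identical copy HSPA1B read 429 ± 270 CPM, so its value is uncertain. In all, 232 genes rose and 297 fell of 14636 tested. Scaling by library size only moved the median gene by 0.23 on the log2 scale and gave 430 higher and 120 lower, and DESeq2 called 8 and 62.

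Among the fixed lists, 7 of 22 replication-dependent histones rose in the CFIm68 knockout and 0 fell (13 and 0 adjusted over the list alone; median log2 1.52, camera adjusted p = 1.32e-09). HIST1H2BK went from 51.2 to 145 ± 14.4 CPM (adjusted p = 0.000872), and HIST2H2BC rose as well. HIST2H2AA3 went from 18.3 to 68.1 ± 12.1 CPM (adjusted p = 0.000631), but it and HIST2H2AA4 are near-identical copies between which reads can be split. Cytosolic ribosomal proteins, many with near-identical pseudogenes, gave 0 higher and 9 lower of 83 (0 and 21 adjusted over the list alone; median -0.38, camera adjusted p = 4.31e-14). RPL22L1 went from 314 to 76.6 ± 27.9 CPM and RPL21 from 2559 to 1028 ± 142 CPM. Oxidative phosphorylation genes gave 0 and 5 of 76 (0 and 14 adjusted over the list alone; median -0.38, camera adjusted p = 1.49e-10), COX5B among them. Glycolysis and hypoxia genes gave 1 and 5 of 18 (1 and 7 adjusted over the list alone; median -0.36, camera adjusted p = 0.000101). LDHA, a lactate dehydrogenase, fell from 1488 to 677 ± 61.9 CPM and PGK1 from 1015 to 487 ± 109 CPM, while ENO2 rose from 35.1 to 106 ± 20.9 CPM. Cholesterol synthesis gave 0 and 2 of 17, IDI1 and INSIG1 (0 and 3 adjusted over the list alone; median -0.42, camera adjusted p = 0.000169). Heat shock gave 0 and 2 of 12, HSPA1A and HSPE1 (0 and 4; median -0.51, camera adjusted p = 0.000167). The unfolded protein and integrated stress response gave 0 and 3 of 15, ATF3, PSAT1 and PHGDH (0 and 4; median -0.37, camera adjusted p = 0.0201). Epithelial genes gave 1 and 0 of 4, KRT8 (2 and 0; median 0.67, camera adjusted p = 0.0255). None of these 8 list calls held with an estimated correlation (adjusted p = 0.489 with an estimated correlation for each), and fry called 0 lists by its directional test (3 at an unadjusted p under 0.05) and 0 by its mixed test. Without CFIm68 knockout line 2 the counts lower were 4 for ribosomal proteins, 3 for glycolysis and 2 for oxidative phosphorylation, which had 8 without line 1. With library size only they were 3, 3 and 1, and DESeq2 called 0 histones.

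The lists without a call in this comparison had camera adjusted p from 0.0666 for hnRNP proteins to 0.891 for CFIm subunits. CDK1, a cell cycle kinase, fell from 278 to 130 ± 27.7 CPM, as the 1 of 24 cell cycle genes that changed. Fibroblast genes gave 1 higher and 0 lower of 7 (FN1), interferon-stimulated genes 1 and 0 of 7 (OAS3), and p53 targets 1 and 0 of 14 (CDKN1A). Immediate early genes gave 1 and 2 of 12, with FOS higher and JUN and MYC lower. Kidney progenitor genes gave 0 and 1 of 13 (EYA1), neuronal genes 0 and 1 of 7 (NEFL), other cleavage and polyadenylation factors 0 and 1 of 17 (PAPOLA), and CFIm subunits 1 and 1 of 3. The hnRNP proteins (18), SR proteins (14), earlier CFIm targets (10), mitochondrially encoded genes (4) and blood cell genes (2) gave 0 and 0. Adjusted over the list alone, immediate early genes gave 2 and 2, neuronal genes 2 and 1, kidney progenitor genes 2 and 1, and the rest the same counts. Median and mean differed in sign for neuronal genes (-0.08 and 0.13), SR proteins (0.03 and -0.08) and p53 targets (-0.002 and 0.16).

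**Figure D4:**
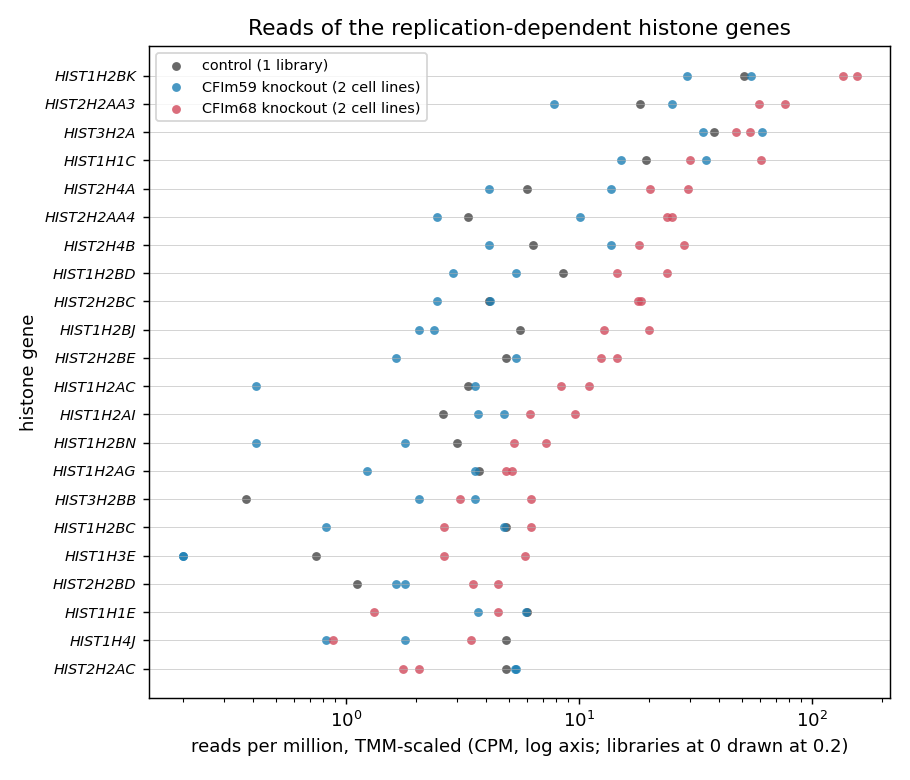
Expression of the 22 measured replication-dependent histone genes in CPM (log axis) in each library of the control, the CFIm59 knockout and the CFIm68 knockout; points are libraries, and those at 0 are drawn at 0.2. HIST1H2BK stands at 51.2 CPM in the control, 42.0 CPM in the CFIm59 knockout and 145 CPM in the CFIm68 knockout.

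In the CFIm59 knockout against the control, several genes without a control read were abundant in both lines. PLP2, a proteolipid of the endoplasmic reticulum, reached 107 ± 8.12 CPM (SD, n = 2; at least 95.5-fold higher, adjusted p = 1.23e-15), and OCIAD2 92.2 ± 5.33 CPM (at least 82.3-fold, adjusted p = 7.87e-15). NOV, a matricellular protein, reached 68.9 ± 14.8 CPM (at least 61.5-fold), and SLFN11, which sensitises cells to DNA-damaging drugs, 64.6 ± 1.14 CPM (at least 57.7-fold). ZNF331, DPYSL3 and the transcription factor SOX11 reached 62.8 ± 3.67, 60.0 ± 6.47 and 48.4 ± 15.3 CPM. SOX11 shares sites with AC010729.1, under which 760 reads of these sites were counted, so the level of SOX11 leaves them out. AC010729.1 stood at 181 ± 65.3 CPM, nearly all from these sites, and its change cannot be assigned to it. In the other direction, RP6-24A23.7 fell from 1069 to 1.92 ± 0.190 CPM (log2 -9.06, SE 0.35, adjusted p = 6.99e-27). IRS4, an insulin receptor substrate, went from 11.9 CPM to 0 (at least 7.91-fold lower, adjusted p = 3.65e-06). MGST1, a microsomal glutathione transferase, fell from 88.9 to 1.51 ± 0.392 CPM (log2 -5.87, SE 0.43, adjusted p = 1.45e-15). ALDH1L2, a mitochondrial folate enzyme, fell from 50.8 to 0.802 ± 0.552 CPM (adjusted p = 5.41e-13), and PPP1R14A, RP6-24A23.6 (in part at shared sites), LA16c-83F12.6 and RP11-527N22.1 were also named. MID1 fell to 44.1 ± 4.21 CPM (log2 -3.14, adjusted p = 8.39e-14) and DDR2 to 1.03 ± 1.45 CPM (adjusted p = 2.35e-09). Between the knockouts they did not pass the test (log2 -0.10 and -0.05, adjusted p of 0.814 and 0.979), and their falls in both rest on the 1 control library. Of 14636 genes, 1022 rose and 1006 fell, 385 and 151 of them by 4-fold or more. The count lower was 624 without CFIm59 knockout line 1 and 617 without line 2, and DESeq2 called 270 higher and 309 lower.

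The unfolded protein and integrated stress response list gave 0 higher and 8 lower of 15 in the CFIm59 knockout (0 and 11 adjusted over the list alone; median log2 -0.97, camera adjusted p = 7.97e-07). XBP1, a transcription factor of the unfolded protein response, fell from 206 to 61.4 ± 20.2 CPM (adjusted p = 1.51e-06), and ATF4, ATF3, ASNS and VEGFA fell as well. Cholesterol synthesis gave 0 and 6 of 17 (0 and 6 adjusted over the list alone; median -0.62, camera adjusted p = 4.52e-06). IDI1 fell from 116 to 25.1 ± 9.25 CPM and INSIG1 from 138 to 35.7 ± 8.57 CPM. Oxidative phosphorylation gave 2 and 19 of 76 (2 and 24 adjusted over the list alone; median -0.44, camera adjusted p = 4.52e-06), with NDUFA1 lower and NDUFS6 higher. Cytosolic ribosomal proteins gave 1 and 22 of 83 (3 and 30 adjusted over the list alone; median -0.41, camera adjusted p = 4.57e-05), with RPL39 from 5209 to 2037 ± 210 CPM. Glycolysis and hypoxia gave 1 and 7 of 18 (1 and 7 adjusted over the list alone; median -0.40, camera adjusted p = 0.00137). BNIP3, a mitophagy receptor, fell from 76.2 to 11.1 ± 0.557 CPM, and NDRG1 rose. None of these 5 held with an estimated correlation (adjusted p = 0.875 with an estimated correlation for ribosomal proteins and 0.671 for the other 4), and fry called 0 lists by its directional test (4 at an unadjusted p under 0.05). Its mixed test, for change in either direction, called 4, the unfolded protein and integrated stress response, heat shock, other cleavage and polyadenylation factors and neuronal genes. Against the same control library, ribosomal proteins, oxidative phosphorylation and glycolysis had medians of -0.38, -0.38 and -0.36 in the CFIm68 knockout, and between the knockouts -0.05, 0.03 and -0.003. Their falls in the 2 knockouts are thus not independent findings and rest on that 1 library. Cholesterol synthesis and the unfolded protein and integrated stress response also fell in the CFIm68 knockout, with medians of -0.42 and -0.37. Between the knockouts their medians were 0.29 and 0.60. The part of their falls common to both knockouts rests on the same control library. Without CFIm59 knockout line 1 the counts lower were 6 for ribosomal proteins and 4 for oxidative phosphorylation, and without line 2 they were 12, 11 and, for the unfolded protein and integrated stress response, 5.

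The lists without a call in the CFIm59 knockout had camera adjusted p of 0.0502 or more. The p53 targets gave 5 higher and 0 lower of 14 (8 and 1 adjusted over the list alone), or 2 higher without CFIm59 knockout line 2. TNFRSF10B, a death receptor, rose from 28.0 to 92.2 ± 11.5 CPM, with BBC3, BAX, FAS and PHLDA3. Fibroblast genes gave 2 and 0 of 7, FN1 and SPARC (3 and 0 adjusted over the list alone), with SPARC at 10 and 153 reads in the lines. Epithelial genes gave 1 and 0 of 4, EPCAM, at 80 and 25 reads, and neuronal genes 1 and 0 of 7, GAP43 (3 and 0). Immediate early genes gave 1 and 3 of 12, with DUSP1 higher and FOSB, FOS and JUN lower (2 and 5). Kidney progenitor genes gave 0 and 3 of 13, SIX2, EYA1 and CITED1, the last from 23.2 to 2.54 ± 1.06 CPM. Cell cycle genes gave 1 and 2 of 24 (TYMS higher, BUB1 and PCNA lower), and mitochondrially encoded genes 2 and 0 of 4 (MT-CO1 and MT-ATP6, with shared reads). Other cleavage and polyadenylation factors gave 1 and 2 of 17 (CSTF2T higher, CSTF2 and PAPOLA lower). Heat shock gave 1 and 3 of 12 (1 and 5), with a median of -0.33 and a mean of 0.34. The 1 heat shock gene higher was HSPA1A, at 1035 ± 53.8 CPM and with a near-identical copy. The hnRNP list gave 1 and 0 of 18, HNRNPUL1 (0 and 0), blood cell genes 0 and 1 of 2 (HBA1), and CFIm subunits 0 and 0 of 3 (0 and 1). SR proteins, earlier CFIm targets, histones and interferon-stimulated genes gave 0 and 0. Where no other pair is given, counts adjusted over the list alone were the same. Median and mean also differed in sign for kidney progenitor genes (0.16 and -0.10), CFIm subunits (0.04 and -0.13) and hnRNP proteins (-0.01 and 0.05).

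Between the knockouts, genes seen in the CFIm59 lines and at 0 reads in the CFIm68 lines were prominent among those lower in the CFIm68 knockout. OCIAD2 was at least 78.2-fold lower (adjusted p = 1.02e-19), SLFN11 at least 54.8-fold (adjusted p = 8.21e-18) and SOX11 at least 41.1-fold (adjusted p = 1.35e-15). CTSZ, a cathepsin, stood at 36.3 ± 4.26 CPM against 0 and was at least 30.8-fold lower (adjusted p = 3.94e-14), and HSPA1A and AC010729.1, the latter with the reads shared with SOX11, were named with them. On the higher side, RP6-24A23.7 stood at 1320 ± 137 CPM in the CFIm68 knockout against 1.92 ± 0.190 CPM (log2 9.37, adjusted p = 1.15e-28). RP6-24A23.6, RP6-24A23.3, RP11-527N22.1, LA16c-83F12.6 and IRS4 (at least 9.73-fold) followed. Of 14636 genes, 1385 were higher and 1503 lower in the CFIm68 knockout. Scaling by library size only moved the median gene by 0.15 and gave 1944 and 1035. The counts were 836 higher without CFIm59 knockout line 1, 760 higher and 918 lower without line 2, and 448 and 596 with DESeq2.

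Histones were higher in the CFIm68 knockout than in the CFIm59 knockout in 13 of 22 genes and lower in 0 (13 and 0 adjusted over the list alone; camera adjusted p = 1.12e-07). The median log2 was 1.54, or 1.49 with genes at 0 set to their bound, and HIST1H2BK stood at 145 ± 14.4 against 42.0 ± 18.1 CPM. The unfolded protein and integrated stress response gave 6 higher and 0 lower of 15 (9 and 0 adjusted over the list alone; median 0.60, camera adjusted p = 0.00189), with XBP1 at 146 ± 7.45 against 61.4 ± 20.2 CPM. Neither held with an estimated correlation (adjusted p = 0.686 with an estimated correlation for each), and fry called 0 lists by its directional test (3 at an unadjusted p under 0.05). Its mixed test called 17 of 21, histones not among them. Without CFIm59 knockout line 2, 6 histones were higher, and without either CFIm59 knockout line 3 genes of the stress response list. The other lists had a camera adjusted p of 0.0867 or more. Kidney progenitor genes gave 4 higher and 0 lower of 13, PAX2, SIX2, SALL1 and CITED1, or 2 without CFIm68 knockout line 2. Cholesterol synthesis gave 5 and 0 of 17, INSIG1 and IDI1 included, but 0 without CFIm59 knockout line 2 and 2 without CFIm68 knockout line 2. The p53 targets gave 2 and 6 of 14, with TNFRSF10B and BBC3 lower and CDKN1A higher, and 2 lower without CFIm59 knockout line 2. Immediate early genes gave 4 and 1 of 12, with FOS, FOSB, JUNB and EGR1 higher, or 2 higher without CFIm59 knockout line 2. Ribosomal proteins gave 3 and 13 of 83 and oxidative phosphorylation 5 and 7 of 76, with 6 and 2 lower without CFIm59 knockout line 2. Without CFIm59 knockout line 1 oxidative phosphorylation gave 3 and 4. Cell cycle genes gave 1 and 5 of 24, or 3 lower without either CFIm59 knockout line. The hnRNP proteins gave 0 and 4 of 18, or 2 lower without either CFIm59 knockout line or CFIm68 knockout line 1. Neuronal genes gave 1 and 3 of 7, mitochondrially encoded genes 0 and 3 of 4, glycolysis 3 and 2 of 18, heat shock 2 and 1 of 12, and other cleavage and polyadenylation factors 2 and 1 of 17. CFIm subunits gave 2 and 1 of 3, epithelial genes 2 and 1 of 4, fibroblast genes 0 and 1 of 7 (SPARC), interferon-stimulated genes 1 and 0 of 7 (OAS3) and earlier CFIm targets 1 and 0 of 10 (VMA21). SR proteins and blood cell genes gave 0 and 0. Adjusted over the list alone, the counts were 6 and 0 for cholesterol synthesis, 3 and 8 for p53 targets, 5 and 2 for immediate early genes, 3 and 14 for ribosomal proteins and 4 and 7 for oxidative phosphorylation. They were 1 and 6 for cell cycle genes, 1 and 1 for other cleavage and polyadenylation factors and 2 and 0 for blood cell genes, and the same as over all genes for the rest. Median and mean differed in sign for kidney progenitor genes (-0.05 and 0.42), glycolysis and hypoxia (-0.003 and 0.13) and oxidative phosphorylation (0.03 and -0.0001).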

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

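All tests weighed here were chosen after the result was seen, except whether 1 CFIm68 knockout library set the histone result. The genes in the next paragraph outside NAB1, SSX2IP, CPSF7 and NUDT21 were also chosen after their values were seen.

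Effects that differed between the knockouts by the test of the difference itself were picked out. In 152 genes the CFIm68 knockout moved to the proximal site, the CFIm59 knockout moved to the distal site, and the difference passed the test. In 4 genes the directions were the reverse. These were all the genes called in opposite directions. Their opposite calls against 1 control made a called difference likely, so that test adds little support. The largest of the 152, among genes with 50 or more reads per library on average, were NAB1 and SSX2IP, with proximal use higher in the CFIm68 than in the CFIm59 knockout by 85.9 and 84.1 percentage points. C12orf49 followed at 82.5 points, with 40% in the control, 6.04 ± 5.60% in the CFIm59 knockout and 88.5 ± 3.64% in the CFIm68 knockout (SD, n = 2). SREK1IP1, whose protein binds the splicing regulator SREK1, followed at 81.1 points, with 46.9%, 10.2 ± 3.56% and 91.3 ± 6.08%. The 4 genes of the reverse kind were PCM1 (74.6% in the control, 90.7% in the CFIm59 knockout and 56.1% in the CFIm68 knockout), PRPF4B (33.3%, 60.6% and 19.6%), RPL23A (83.8%, 94.5% and 65.5%) and RPL37A (99.3%, 99.9% and 97.4%). In expression, CPSF7 was higher in the CFIm68 than in the CFIm59 knockout by 1.42 on the log2 scale, and NUDT21 by 0.88.

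The first pattern was that 93 genes averaged 10 CPM or more in the CFIm59 knockout lines, with 5 or more in each, and had 3 reads or fewer in the control, PEG10, PLP2, OCIAD2 and HES5 among them, and 23 the other way, MGST1 and ALDH1L2 among them, against 4 and 7 in the CFIm68 knockout. Gain or loss of whole chromosomes was weighed as the whole source. It was argued against for 48 of these 116 genes (41.4%). They lay on chromosomes whose median log2 change was within 0.1 of 0. That share was not set against the share of all tested genes on such chromosomes, so it does not address a partial role. Such chromosomes hold many tested genes, 1482 on chromosome 1 and 981 on chromosome 2 among them, so a sizeable share was likely in advance. This test replaced an earlier one over all called genes, seen first. There 523 (25.8%) kept a 4-fold change after the chromosome median was subtracted. That earlier test could not decide, since the largest chromosome median was 0.50, too small to undo most 4-fold changes. A shallow control was argued against too, as 75 genes at 0 control reads would have had 10 or more at the level of the lower line. Of the genes at 10 CPM or more in line 1 and 3 reads or fewer in the control, 70.6% (72) were also at 10 CPM or more in line 2, which loss of CFIm59 and a shared founder cell would both give, so these cannot be told apart without a line in which CFIm59 is put back.

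The second pattern was the move to distal sites in the CFIm59 knockout, 316 genes against 60. If a chance deviation of the lone control were its only source, these genes would move to distal in the CFIm68 knockout as well. Instead their median log2 change there lay above that of the other tested genes by 0.71 (bootstrap 95% interval 0.43 to 0.92; medians 1.30 and 0.59), although a real effect of CFIm68 loss on the same genes could hide part of such a deviation. Sites classed outside last exons were argued against as the whole source, since 85.8% of these genes (271) had both sites classed as last exon. For pairs with an intron site this stays open, since the share to distal was 5.80% in last exon pairs and 4.85% in these pairs (43 of 886), a difference of 0.944 points (Fisher's exact p = 0.302). These 2 tests replaced an earlier one, seen first, of last exon pairs against all other pairs (2.03 points higher, Fisher's exact p = 0.00499), in which 302 pairs of an upstream exon and a last exon site, at 0.662%, lowered the second share. The last exon class held 4675 of all 5869 tested pairs, and the 2 sites of such a pair need not share an exon. They lay 58545 nt apart in WDR33 and 34415 nt apart in PAPOLA, both called to distal. Whether the proximal site of such pairs lies inside an intron of a longer transcript was not tested. Internal priming within last exons and an effect of CFIm59 loss itself stay open.

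The third pattern was the higher level of polyadenylated histone reads in the CFIm68 knockout, a CPM sum over 22 genes of 201 in the control, 268 and 126 in the CFIm59 knockout lines and 563 and 442 in the CFIm68 knockout lines. A larger share of cells in S phase was argued against, since 13 S-phase genes had a median log2 change of 0.12 (bootstrap 95% interval -0.04 to 0.17) against 1.52 for the histones. A single library was argued against as well, since the median was 1.26 and 1.67 with either CFIm68 knockout line left out. With oligo(dT) priming the reads may come from histone transcripts ended by polyadenylation in place of their stem-loop, which was not tested, and an effect of CFIm68 loss and of the founder cell stay open.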

How the results depend on the processing

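The alternatives on site class, shared sites, library size and mitochondrial genes were chosen after the results were seen; the others were planned. Of 1092 values of named genes over 92 genes and comparisons, 1032 kept direction and side of the threshold, 50 lost the call and 10 reversed. The 1032 include 48 from merging sites within 40 nt, which left the pairs as they were. Genes that a setting left untested were not counted, and 13 values remained at minimums of 100 and 20 reads. The named genes were chosen for large changes, so the share kept does not stand for other genes. The reversals came from settings that pair other sites of the gene. With last exon sites only, log2 was 3.31 for AEBP2 in the CFIm68 knockout against the control and 2.79 between the knockouts, and -2.15 for CTD-2006C1.2, -2.45 for MPP6 and 0.23 for SLIT2 in the CFIm59 knockout. With the most proximal and most distal site it was 1.16 for EXOC8 and 0.92 for RIF1 in the CFIm68 knockout, and 3.41 for GCFC2, 2.78 for KIAA1524 and 0.73 for RIF1 between the knockouts. For the counts below, to proximal then to distal or higher then lower, the cause was not tested unless stated. DESeq2 called 752 and 38 site changes in the CFIm68 knockout, 8 and 14 in the CFIm59 knockout, and 190 to distal between them. In expression it called 8 and 62, 270 and 309, and 448 and 596. All 790 site changes that DESeq2 called in the CFIm68 knockout and all 22 in the CFIm59 knockout were among those of edgeR. Minimums of 100 and 20 reads left fewer genes to test and gave 518 and 85, 36 and 203, and 752 and 148. No minimum beyond 1 read gave 114 to distal in the CFIm68 knockout and 34 and 128 in the CFIm59 knockout. A change of 15 points or more, which removes calls by construction, left 39 to proximal in the CFIm59 knockout and 238 to distal between the knockouts. The most proximal with the most distal site gave 108 to distal in the CFIm68 knockout, 39 to proximal in the CFIm59 knockout and 206 to distal between them. diffSpliceDGE over all sites gave 18 and 51 in the CFIm59 knockout. A 2-fold minimum, which also removes calls by construction, left 618 lower in the CFIm59 knockout and 789 and 922 between the knockouts. Library size only gave 430 and 120 in the CFIm68 knockout. Leaving out each knockout library in turn, with the lone library left in a group assumed to vary like the others, gave ranges. For site use they were 1236 to 1471 and 170 to 183 in the CFIm68 knockout, 35 to 89 and 129 to 426 in the CFIm59 knockout, and 1913 to 2296 and 235 to 318 between them. For expression they were 210 to 290 and 264 to 331, 717 to 1224 and 617 to 1175, and 760 to 1178 and 918 to 1278. The covariance of the site changes was -0.406 with 100 and 20 reads and -0.201 to -0.0990 with a library left out. Lists called by camera, 8, 5 and 2, came to 0 with an estimated correlation and 0 with fry's directional test in each comparison. Fry's mixed test, for change in either direction, called 0, 4 and 17. The same replicate number names different cell lines, and samples with the same number did not deviate together (correlation 0.0317 for site use and -0.0213 for expression). A replicate block over the 4 knockout libraries gave 2392 and 378 site changes, against 2383 and 363 without it, and 1149 and 1316 genes in expression, against 1347 and 1535. Merging sites within 40 nt gave the same site pairs and so tested nothing. The test of UGUA near sites and its other windows were not run, because the sequence was not analysed here. The simulated tests, with few changed genes, found few changes of log2 1 in site use. They do not give the recovery in the data, but small changes are not excluded.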

Other observations

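The values and groupings below were chosen after the data were seen, except the test of site shift against expression.

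The loss of IRS4 reads in the CFIm59 knockout extended to its neighbours on chromosome X. IRS4 and RP6-24A23.3, RP6-24A23.6 and RP6-24A23.7 lie together between 107960335 and 107984508 (hg19), where 60 sites with reads held 3318 reads in the control, 4 and 7 in the CFIm59 knockout lines and 4764 and 3031 in the CFIm68 knockout lines. Most came from RP6-24A23.7, with 2864 reads in the control, 3 and 5 in the CFIm59 knockout lines and 4105 and 2775 in the CFIm68 knockout lines. RP6-24A23.6 and RP6-24A23.7 are on the strand of IRS4. COL4A5, a collagen gene beside them (107689113 to 107944489), held 65 reads in the control, 42 and 49 in the CFIm59 knockout lines and 94 and 45 in the CFIm68 knockout lines.

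Here a gene was called present in libraries where it averaged 10 CPM or more, with 5 CPM or more in each, and called near absent in libraries with 3 reads or fewer in each. Genes present in both CFIm59 knockout lines and near absent in both the control and the CFIm68 knockout numbered 43, among them PEG10, OCIAD2, SLFN11 and SOX11. Genes present in the control and both CFIm68 knockout lines and near absent in the CFIm59 knockout numbered 12, among them MGST1, the transcription factors PRDM16 and SALL3, and IRS4. Genes present in the control and near absent in the CFIm68 knockout were BEX1, DDR2 (3 reads in each line), ALB and the cancer-testis genes CT45A2, CT45A5, CT45A6 and SAGE1. Of these, ALB and CT45A5 were also near absent in both CFIm59 knockout lines, and DDR2 fell there too. Their losses in both knockouts rest on the lone control library. Chromosome medians of the log2 change also moved. In the CFIm59 knockout they were 0.50 for chromosome 19 (bootstrap 95% interval 0.45 to 0.54), 0.39 for chromosome 9 (0.33 to 0.47) and -0.39 for chromosome 22 (-0.45 to -0.29). In the CFIm68 knockout they were -0.34 for chromosome 13 (-0.39 to -0.30), 0.24 for chromosome 11 (0.19 to 0.29) and 0.23 for chromosome 9 (0.19 to 0.29). Chromosome 9 was thus higher in both knockouts against the same control library. These intervals resample the genes of a chromosome and hold no spread between cell lines or of the lone control.

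A hypothesis held that genes moved to proximal sites in the CFIm68 knockout would be more highly expressed. It was not borne out. The median log2 expression change was -0.04 in the 1483 genes moved to proximal and -0.03 in 4202 tested genes without a call, a difference of -0.0105 (permutation test, 100000 permutations, 2-sided, p = 0.506).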
